A study of Homo sapiens and Mus musculus with 8 samples.

How the data were processed

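Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts adapters into open DNA, in 2 lines of fusion-negative rhabdomyosarcoma, a tumour of skeletal muscle lineage. RD18 is a human line and KMR46 is a mouse line made with a muscle-specific Cre, loss of p53 and an activated Kras. Each line had 2 vehicle libraries and 2 libraries transfected with miR-449a and miR-340-5p, all taken 60 hours after transfection. Groups were taken from the sample titles. Nothing in the labels says whether the replicates came from separate cultures.

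The authors deposited 4 region lists, 1 of opened and 1 of closed regions per line. Their names give the line and open or closed, but no sample or contrast. Opened was therefore read as more accessible with the microRNAs than with vehicle, and closed as less. Each list holds a chromosome, a start, an end, a whole region number, a constant 0 and no strand. No fold, p-value, count or signal is given per region or per library, so the depth behind each region is unknown, the size of each change is not known here, and no replicate error can be attached to any region. Per the submitters' processing notes, DiffBind 3.0.15 and deepTools 3.4.3 were used, and the builds GRCh38 and mm10 were named. The roles of these tools, the aligner, the peak caller and the significance threshold are not given in the sources used here. The human lists were read as GRCh38 and the mouse lists as mm10, the only human and mouse builds named. Starts were converted to 1-based positions.

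Within each line the region number rose with position over the opened and closed lists together, with chromosomes sorted as text, and no number occurred more than once. It was therefore read as the rank of a region in the authors' position-sorted set of regions, which must hold at least as many regions as the largest number. The number of ranked regions on a chromosome was bounded by the listed ranks on either side of its borders. For the last chromosome, X in KMR46, the largest gap between listed ranks on that chromosome was added. No later rank borders it, so its upper value is an estimate and not a bound.

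Human regions were placed on the RefSeq gene table of GRCh38.p14, with 19974 protein-coding genes on chromosomes 1 to 22 and X. That table gives gene spans without strand, so transcription start sites were not known, and both ends of a gene span stood in for them. The planned tests were written for start sites, and the distance to a gene span or to a gene end was used in their place. Each region midpoint was assigned to the nearest protein-coding gene span within 100 kb, and inside overlapping spans to the gene with the nearer end. No genome sequence and no mouse annotation was used here. Random positions were for that reason not matched on GC content, and the planned motif tests, the gene tests in KMR46 and the comparison of genes between lines were not run. The random positions were drawn evenly between the first and last annotated gene of each chromosome. Assembly gaps and sequence in which no region can be called were not left out.

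The 24 gene lists, with 819 entries that all matched the table, were fixed before the data were examined, and former symbols of a gene were counted once with its present one. They are YAP/TEAD targets and cofactors, sarcomere and muscle differentiation, myogenic factors, satellite cell and progenitor genes, fibroblast and matrix, factors and adhesion genes of the epithelial-mesenchymal transition, smooth muscle, neuronal, epithelial, endothelial, immune, cartilage and bone, adipogenic, RAS/MAPK feedback, AP-1 family, TGF-beta and BMP, Notch, Wnt, interferon, p53 and senescence, cell cycle, focal adhesion and actin, SWI/SNF, and targets of miR-449 and miR-340 from general knowledge. The count of opened regions assigned to a list was compared with 10000 sets of random positions drawn from 1000000 positions and matched per region on the class of distance to a gene (inside, up to 10 kb, 10 to 100 kb, over 100 kb). The one-sided empirical p, whose smallest value is 0.0001, was adjusted by Benjamini-Hochberg over the 24 lists. The authors' set of all accessible regions is not analysed here, so these tests compare opened regions with the genome and not with other accessible regions.

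Shares were compared with Fisher's exact test, two-sided, with exact Clopper-Pearson intervals at 95%, which cover counting error only. Chromosomes were tested with exact binomial tests, two-sided, that used the bound on the ranked regions least favourable to a difference. For an excess on the X chromosome the estimated upper value took the place of a bound. Opened regions adjacent in rank were counted against 10000 random draws of ranks. For local density, the intervals between neighbouring opened regions of KMR46 were sorted into 3 equal classes by the density of ranked regions in the 5 intervals to each side. The listing rate of each class was compared with 10000 permutations that shifted the intervals round each chromosome. A first form of this test, against random ranks, called too many simulated sets and was discarded before use on the data. Differences of medians were tested with permutation tests, two-sided, of 100000 permutations. The n given beside a p counts regions, not libraries. Regions of a list are not independent samples, and p-values over regions do not measure the spread between libraries or cultures. The rank tests in KMR46 and the comparison of closed with opened regions of RD18 were chosen after the lists had been examined.

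The tests were tested on simulated data. With 140 simulated regions, of which 7 were planted near YAP/TEAD genes, that list was called in 100% of 100 sets. The list and the number planted equal those of the result, so power for other lists or fewer regions is not known. With none planted, any list was called in 2% of sets. These sets were random genome positions, so the error rate for accessible regions is not known. The density test called 6% and the adjacency test 5% of randomly listed KMR46 sets. These sets were random draws of ranks, as in the adjacency test itself, so its rate was fixed near 5% by design. They did not hold the clustering of the opened list, so the error rate of the density test for such a list is not known. In sets listed more often where regions were sparse, the density ratio recovered averaged 1.15 where the true ratio averaged 2.20, so it can understate a difference.

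The genes named are, by the rule fixed in advance, all genes assigned to closed regions of RD18, the 10 genes with the most opened regions of RD18 (ties by distance, then symbol), and up to 15 members of the gene lists, taken in order of list p. In KMR46, for which no annotation was used, the 5 longest runs of regions within 50 kb are named by position, ranked by number of regions and then by length. The rule's part on genes near opened regions in both lines could not be applied. LRRC8C, SMYD2, CCN2 and ANKRD1 fall outside the rule and were chosen after their values were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The alternatives were the distance limit, the gene assignment, the matching of random positions, the merging of regions within 50 kb, the distance that counts as a gene end, and the windows of the rank tests.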

Results

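The series asked how chromatin accessibility changed in fusion-negative rhabdomyosarcoma cells after joint transfection of miR-449a and miR-340-5p, compared with transfection vehicle alone. Accessibility was profiled 60 hours after transfection in the human line RD18 and the mouse line KMR46, with 2 libraries per group in each line. The measurements given here are the authors' lists of open and closed differential regions. The lists are named without a contrast and were read as opened or closed in microRNA-treated against vehicle cells. They carry positions without counts, so the depth and the fold change behind each region are unknown.

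In both lines, the regions called different were nearly all regions that opened with the microRNAs. In RD18, 140 regions opened and 6 closed. In KMR46, 2778 regions opened and 69 closed. Opened regions made up 95.9% of the differential regions of RD18 (exact 95% interval 91.3% to 98.5%) and 97.6% of those of KMR46 (exact 95% interval 96.9% to 98.1%). These shares did not differ detectably between the lines (odds ratio, RD18 over KMR46, 0.58, Fisher's exact test, two-sided, p = 0.179). The largest region number was 84406 in RD18 and 131818 in KMR46. The opened regions were thus at most 0.166% of the numbered regions of RD18 and at most 2.11% of those of KMR46, and the closed regions at most 0.0071% and 0.052%. The 2 lines were not normalised or tested together, and the number of regions passing a threshold depends on library depth and replicate spread, which the lists do not give. The opened share can also depend on how treated and vehicle libraries were normalised and on their signal quality. Neither is given, so a general opening cannot be told apart from such a difference. Nearly all regions were 401 bp wide, including 135 of 140 opened regions in RD18 and 2755 of 2778 in KMR46.

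In RD18, the 6 closed regions lay at the ends of protein-coding genes, and few of the opened regions did. By the coordinates in the authors' deposited table (GRCh38), the closed regions were at MVD, an enzyme of the mevalonate pathway (chromosome 16, 88663028 to 88663428), UBE2I, the SUMO-conjugating enzyme UBC9 (chromosome 16, 1308956 to 1309356), MIER2 (chromosome 19, 344602 to 345002), ATAD3A, a mitochondrial membrane ATPase (chromosome 1, 1511870 to 1512270), PUSL1, which also had an end of ACAP3 within 1 kb (chromosome 1, 1308229 to 1308629), and BAG5, a co-chaperone, beside COA8 (chromosome 14, 103562529 to 103562929). Their midpoints were 4 to 168 bp from the nearest gene end. Of the 140 opened regions, 3 (2.14%, exact 95% interval 0.444% to 6.13%) were within 1 kb of a gene end, those at ARL6, LRRC8C and SMYD2 (the last 2 named after their values were seen), compared with 6 of 6 closed regions (100%, exact 95% interval 54.1% to 100%). This difference passed Fisher's exact test, two-sided (p = 6.93e-09), and was examined after the values were seen. The share of opened regions at gene ends was 2.14% where random positions gave 2.40% (ratio 0.89), and it passed the empirical test in neither direction (n = 140 opened regions, one-sided p = 0.66 for higher and 0.564 for lower). Within 3 kb the shares were 3.57% and 6.51% (n = 140 opened regions, ratio 0.549, one-sided p = 0.103 for lower), and with the ends of all annotated genes 9 opened regions (6.43%) were within 1 kb. Accessible regions in general lie nearer to transcription start sites than random positions do. The shares therefore do not tell how opened or closed regions compare with other accessible regions.

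**Figure D1:**
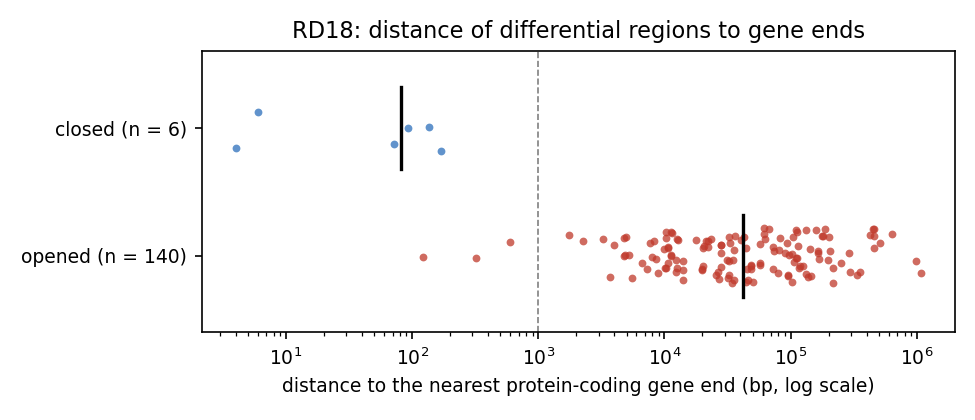
Distance from each differential region of RD18 to the nearest end of a protein-coding gene, in bp on a log axis, with 1 point per region, black bars at the medians and a dashed line at 1 kb. The 6 closed regions lie within 168 bp of a gene end, and the 140 opened regions have a median distance of 41.6 kb.

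The opened regions of RD18 were mostly inside genes or at a distance from them. Of the 140, 60 (42.9%) were inside a protein-coding gene span, 11 (7.86%) were within 10 kb of one, 39 (27.9%) were between 10 and 100 kb away, and 30 (21.4%) were over 100 kb away. The 110 regions with a gene within 100 kb were assigned to 106 genes. LSAMP, which encodes a cell adhesion protein of the immunoglobulin superfamily, had the most, with 3 opened regions, of which 2 lay inside the gene and 1 lay 11.4 kb outside it. CCN1 and the uncharacterised gene LOC124904930 had 2 each. The other genes had 1, and those next by the naming rule were ADAM22, AGK, AGTPBP1, AKAP6, ANKS1B, ANO4 and ARL6, each with the region inside its span. AKAP6 anchors protein kinase A at the nuclear envelope of muscle cells.

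Genes linked to YAP and TEAD, the transcriptional effectors of the Hippo pathway, stood out among the 24 gene lists tested. In RD18, 7 opened regions were assigned to 6 of the 34 genes of this list, where matched random positions gave 0.357 on average (95% of random sets 0 to 2). The ratio was 19.6 (n = 140 opened regions, empirical one-sided p = 0.0001, the smallest the random sets can give, Benjamini-Hochberg adjusted p = 0.0024). CCN1, a secreted matricellular protein and a standard YAP target, had 2 opened regions 23.4 and 28.1 kb from its span (chromosome 1, 85607182 to 85607582 and 85611887 to 85612287 in the authors' deposited table). CRIM1, a transmembrane protein that binds BMPs, had 1 inside its span (chromosome 2, 36438397 to 36438797). VGLL2, a TEAD cofactor of skeletal muscle, had 1 at 33.1 kb (chromosome 6, 117232215 to 117232615). GADD45A, a stress response gene, had 1 at 32.2 kb (chromosome 1, 67652833 to 67653233), ASAP1, an ARF GTPase-activating protein, had 1 at 48.1 kb (chromosome 8, 130491589 to 130491989), and IGFBP3, an IGF-binding protein, had 1 at 57.1 kb (chromosome 7, 45978171 to 45978571). The other 28 genes of the list, among them CCN2 and ANKRD1, also named after their values were seen, had no opened region assigned. With the distance limit set to 10 kb only CRIM1 remained, and the list was no longer called (n = 140 opened regions, ratio 4.45, adjusted p = 1). The comparison is with the genome and not with other accessible regions, and random positions were not matched on chromosome.

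**Figure D2:**
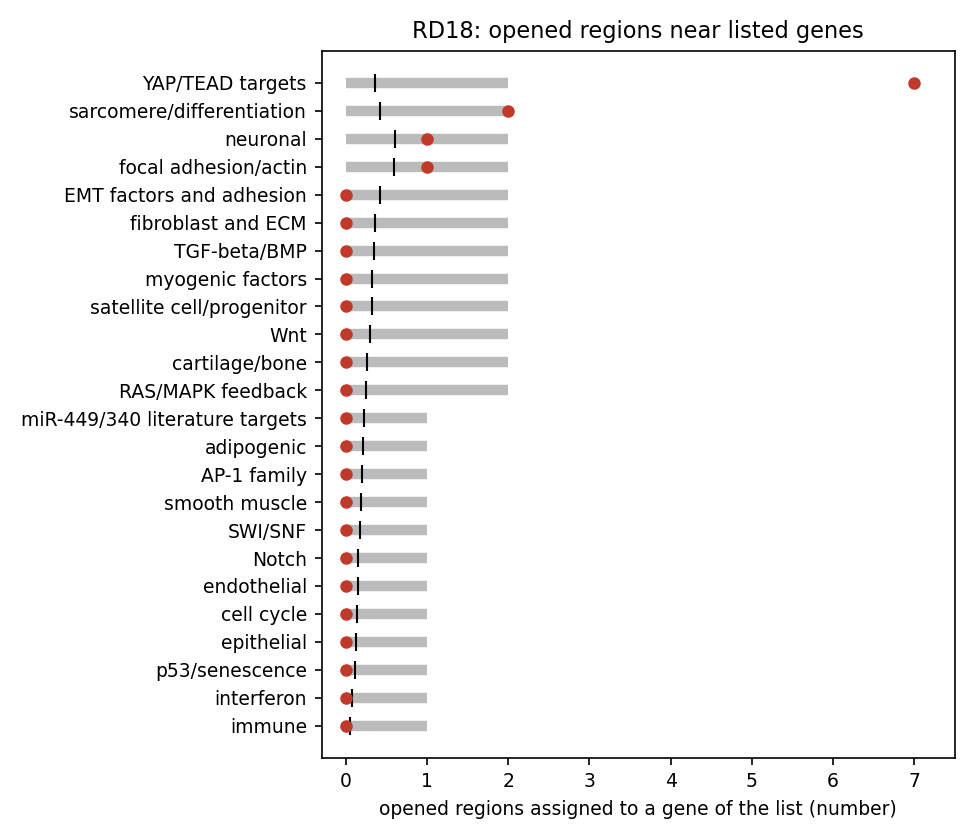
Number of opened regions of RD18 assigned to each of the 24 gene lists (red points), with the mean (black ticks) and the central 95% (grey bars) of 10000 sets of matched random positions. The YAP/TEAD list, with 7 regions, is the only list whose point lies beyond the bar.

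**Figure D3:**
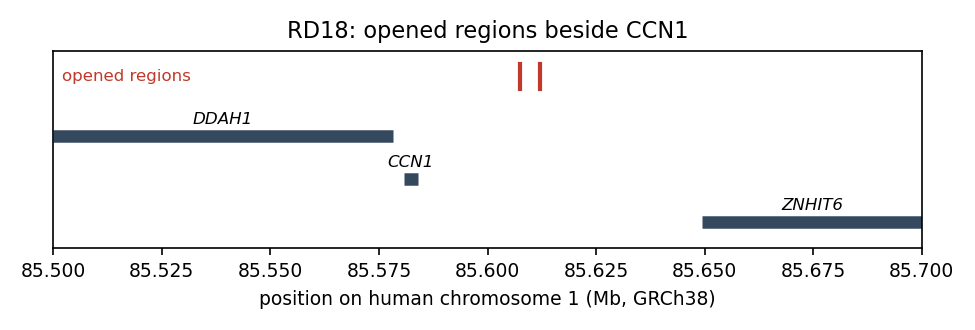
The 2 opened regions of RD18 beside CCN1 on human chromosome 1, with positions in Mb on GRCh38 and protein-coding gene spans as dark bars. The regions lie 23.4 and 28.1 kb beyond CCN1, between it and ZNHIT6.

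No other list passed the test in RD18. The sarcomere and differentiation list had 2 of its 79 genes, TRIM55 with a region inside its span and MYOZ2, a Z-disc protein, with one at 32.4 kb (n = 140 opened regions, 0.419 expected, ratio 4.77, empirical p = 0.0652, adjusted p = 0.782). The neuronal list had 1 region, inside MAP2, a microtubule-associated protein (n = 140 opened regions, 0.607 expected, adjusted p = 1). The focal adhesion and actin list had 1 region, 22.1 kb from CAV1, a structural protein of caveolae (n = 140 opened regions, 0.588 expected, adjusted p = 1). The other 20 lists had no opened region assigned. These were the lists of myogenic factors, satellite cell and progenitor genes, fibroblast and matrix, epithelial-mesenchymal transition, smooth muscle, epithelial, endothelial, immune, cartilage and bone, adipogenic, RAS/MAPK feedback, AP-1 family, TGF-beta and BMP, Notch, Wnt, interferon, p53 and senescence, cell cycle, SWI/SNF, and miR-449 and miR-340 target genes. The expected number was under 1 for each of them, so a lack of opened regions was not detectable. In all, 11 of the 140 opened regions were assigned to a gene of any list.

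In KMR46 the opened regions were adjacent to one another more often than random draws. Among the 2778 opened regions 147 pairs were adjacent in the authors' numbering, where random draws of as many regions gave 58.5 on average (95% of draws 44 to 74, ratio 2.51, empirical one-sided p = 0.0001, the smallest possible). The median distance within these pairs was 3.76 kb. Merging opened regions within 50 kb of each other joined 778 of them and left 2346 loci, for which no random expectation was computed. Over both lists there were 149 adjacent pairs, of which 147 joined 2 opened regions, 2 joined an opened and a closed region, and 0 joined 2 closed regions. Permuting the directions gave 7.00 mixed pairs on average (permutation test, one-sided, p = 0.0271).

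The longest runs of opened regions within 50 kb in KMR46 are given by position in mm10, and no gene is assigned to them here. By the authors' deposited table, the longest lay on chromosome 10 from 21587030 to 21675353, with 6 opened regions among 15 numbered regions in 88.3 kb. Of 6 runs with 5 opened regions, the 4 with the longest span lay on chromosome 13 from 113162423 to 113259590, on chromosome 1 from 81950137 to 82041738, on chromosome 14 from 21229267 to 21318779, and on chromosome 1 from 170015863 to 170088643. In them, the opened regions were 31.2%, 38.5%, 35.7% and 26.3% of the numbered regions.

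Chromosomes of KMR46 differed in how often their numbered regions opened. On the X chromosome 134 regions opened, 42.6 per 1000 numbered regions, where 66.3 were expected from the number of regions on it (ratio 2.02, exact binomial test, two-sided, adjusted p = 1.75e-11 over 20 chromosomes). Chromosome 13 had 192 opened regions (135.7 expected, ratio 1.42, exact binomial adjusted p = 7e-05). Chromosome 15 had 82 (136.1 expected, ratio 0.60, exact binomial adjusted p = 1.81e-05). Chromosomes 1 and 10 (ratios 1.21 and 1.27) were higher and chromosome 11 (ratio 0.73) was lower, but these 3 no longer passed when neighbours within 50 kb were merged (exact binomial adjusted p = 0.0985, 0.111 and 0.109). With this merging the X chromosome and chromosomes 13 and 15 still passed, with weaker values (exact binomial adjusted p = 6.96e-09, 0.0253 and 0.00046). Closed regions were in excess on chromosome 2, with 15 where 5.6 were expected (ratio 2.66, exact binomial adjusted p = 0.00872), and none was on the X chromosome, where 1.6 were expected (exact binomial adjusted p = 0.908).

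**Figure D4:**
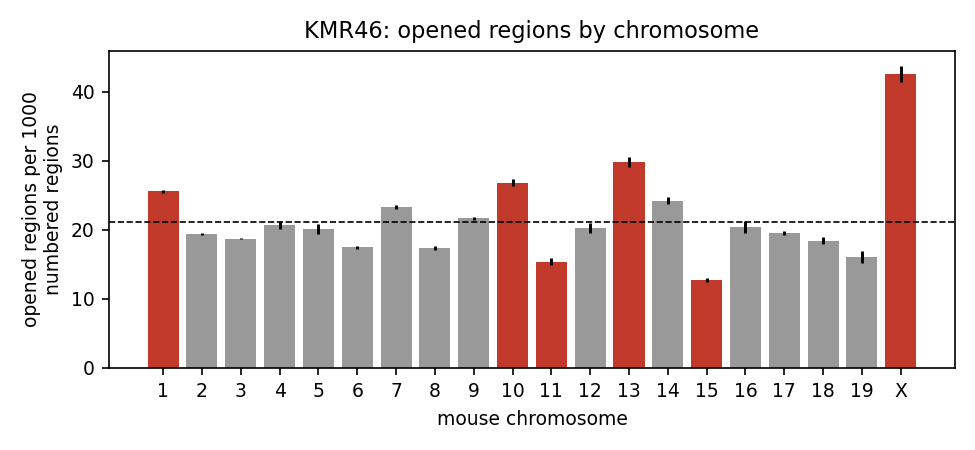
Opened regions of KMR46 per 1000 numbered regions on each mouse chromosome, with vertical lines for the range that the uncertain chromosome borders allow and a dashed line at the value over all chromosomes. For the X chromosome the lower end of this range is an estimate. Red bars mark the 6 chromosomes past an adjusted p of 0.05. The X chromosome stands at 42.6 and chromosome 15 at 12.7.

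Opened regions of KMR46 were also more frequent where numbered regions were sparse. In the sparsest of 3 equal classes of intervals between opened regions, 25.2 per 1000 numbered regions opened, and in the densest class 18.8 per 1000 (ratio 1.34, 95% of shifted data 0.945 to 1.23, permutation test by shifts, two-sided, p = 0.002). The classes pooled all chromosomes, so differences between chromosomes can add to this ratio. The shifts kept each interval on its chromosome, so the ratio is to be read against the shifted range and not against 1. With the density taken over 3 in place of 5 intervals to each side the ratio was 1.15 and no longer passed (permutation test, two-sided, p = 0.337). The density around closed and opened regions did not differ detectably, with medians of 68.1 numbered regions per Mb around closed regions (quartiles 53.8 and 87.2) and 68.8 around opened regions (quartiles 52.9 and 83.7, ratio 0.99, permutation test, two-sided, p = 0.825).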

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

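Of 30 alternatives, 24 kept their result. For a test this means the same direction and side of the threshold, and for a count only a similar size. Each alternative of the gene list test enters both as the number of lists passed and as the YAP/TEAD ratio, so the alternatives are not independent. With a distance limit of 10 kb, 0 of the 24 lists passed and 0 had an unadjusted p under 0.05, where 1 did with 100 kb. The YAP/TEAD ratio was then 4.45 (n = 140 opened regions, adjusted p = 1), since 6 of the 7 regions lie beyond that limit. In the other 6 alternatives this ratio was 17 to 23.5 (n = 133 loci or 140 regions) with adjusted p = 0.0024. Merging neighbours within 50 kb left 3 chromosomes of KMR46 past the threshold for opened regions in place of 6. The ratio of local density, closed over opened, changed sides at 1.02 with a window of 500 kb and 1.05 with 2 Mb, with permutation p = 0.637 and 0.359, neither past the threshold, and the listing rate ratio was 1.15 with 3 intervals to each side; the cause was not tested. With the 1 Mb window the density ratio was 0.99 and also did not pass. The alternatives for the rank tests, the nearest gene end, the matching on gene number and the comparison of closed with opened regions of RD18 at gene ends were chosen after seeing the data. No paired analysis was possible because the lists hold no value per replicate, and for the same reason no replicate could be left out. No stricter threshold was applied, since the score in the lists is constant. The alternatives for motifs, for GC matching, for genes and promoters of KMR46 and for genes shared between the lines were not run.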

Other observations

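The genes and regions in this paragraph were chosen after their values were seen. In RD18, 3 opened regions lay together on chromosome 1 between 59151047 and 59178762 (GRCh38), a span of 27.7 kb that holds 4 numbered regions. The nearest of them lay 367 kb from JUN, a subunit of the AP-1 transcription factor, and the nearest to FGGY, their nearest protein-coding gene, lay 118 kb from it, so they counted for no list. Past the 100 kb limit, opened regions also had PAX3 (202.5 kb) and MYT1L (334.2 kb), both on the list of myogenic factors (PAX3 also on that of satellite cells), and TGFB2 (216.1 kb), on the YAP/TEAD and TGF-beta lists, as their nearest protein-coding gene. Without a distance limit the list of myogenic factors had 2 regions (n = 140 opened regions, 0.447 expected, empirical p = 0.0786, adjusted p = 0.629). These were the regions of PAX3 and MYT1L. MYT1L is a neuronal factor although the list holds it, so only the PAX3 region has a myogenic factor as its nearest protein-coding gene.

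The closed regions of RD18 lay among more genes than the opened ones, a comparison also chosen after the values were seen. The median number of protein-coding genes within 500 kb was 42 around closed and 5 around opened regions (permutation test, two-sided, p = 1e-05, the smallest that 100000 permutations can give). The opened regions had 5.97 such genes on average and random positions 6.99, a difference that did not pass (n = 140 opened regions, empirical two-sided p = 0.137). Against the numbered regions, chromosomes 16 to 19 together had 1 opened region where at least 6472 of the 84406 numbered regions would give 10.7, and 3 of the 6 closed regions. These chromosomes were chosen for their low counts, so no p is given, and chromosome 1, with 2 closed regions, had 22 opened ones.

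Of the tests of explanations that follow, the merging of neighbours was planned before the data were examined, but what it would show was set down after the YAP/TEAD regions had been seen. The other tests, matching on gene number among them, were chosen after the lists had been examined. Opened regions of RD18 lay near YAP/TEAD genes 19.6 times as often as matched random positions. The tables argue against repeated counting of neighbours within 50 kb, since with these merged the ratio was 17.3 (n = 133 loci, empirical adjusted p = 0.0024). Of the regions of this list, only the 2 at CCN1 merged. Clustering over longer distances was not tested, and random positions were not matched on chromosome. Chromosome 1 had 22 opened regions, among them those of GADD45A and CCN1, so these may not be independent. With random positions matched on local gene number the ratio was 18.02. Opened regions and random positions had the same median number of genes, 5, so this matching had little to change. It stays open whether accessible regions of these cells in general lie near these genes. The 5% of opened regions near the list cannot be told apart from that, since the set of all accessible regions was not analysed here. A candidate explanation, as a hypothesis, is that the microRNAs opened distal elements used by TEAD factors; a search for TEAD motifs needs the genome sequence and was not run.

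Closed regions of RD18 lay at gene ends and few opened regions did. A candidate technical explanation is that treated and vehicle libraries differed in the share of reads at promoters. The prediction set down for it was that closed regions lie in denser surroundings in KMR46 too. There the ratio of local density, closed over opened, was 0.9895 (permutation p = 0.825), and 1.02 and 1.05 in other windows. These values cannot decide the question for RD18. The KMR46 libraries are separate ones, and the density of numbered regions does not measure promoters. The 6 closed regions of RD18 are too few to test within. A real loss of accessibility at these gene ends with the microRNAs stays open and untested.

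Opened regions of KMR46 were adjacent in the authors' numbering 2.51 times as often as random draws. Accessible regions split into neighbours up to 2 kb apart do not account for all of it. The adjacent pairs over 2 kb apart alone were 1.728 times the number of all pairs expected (n = 2778 opened regions, empirical p = 0.0001, the smallest possible). The median distance within all adjacent pairs was 3.76 kb, so wider domains split into regions further apart stay untested. Uneven spread over chromosomes does not account for all of it either, since draws within chromosomes gave a ratio of 2.381. Joint opening of elements of the same locus may be the biological counterpart, as a hypothesis. A test of it, or of a copy number gain that differs between libraries, needs the signal of each region in each library and was not run.

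The row order of the opened list of KMR46 is not explained by its sources, but it was not random with respect to position. Over the 147 adjacent pairs the row numbers of both members had a Pearson correlation of 0.229 across pairs (permutation test, two-sided, p = 0.00582). The 23 regions wider than the usual 401 bp had a median row of 1031 against 1394 for the others. That difference concerns width and not position, and it was not tested.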
